A study of Homo sapiens with 4 samples.

How the data were processed

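RNA from 4 cultures of MCF7, an established estrogen receptor-positive breast cancer cell line, was sequenced: 1 control library and 1 library each after 6, 12 and 24 h in medium of pH 6.6. Per the labels' protocols, RNA was extracted with an RNeasy column kit and libraries were made with a SMARTER mRNA-Seq kit. The labels state neither the pH of the control medium, the time at which the control was harvested, nor whether the libraries keep the strand. The submitters' processing notes list mm10, a mouse build, whereas the transcript identifiers in the deposited table are human Ensembl identifiers. The aligner, assembler and quantifier are not given in the sources used here. The names of unannotated transcripts begin with MSTRG, which is the default prefix of StringTie.

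The authors deposited 1 table of 19870 long non-coding transcripts, of which 14924 were annotated and 4946 were assembled without an annotated counterpart. For each library the deposited table holds FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of the library) and the coverage signal per base of the transcript, and 0.0001 stands in place of 0 in both columns. The deposited score columns hold 2 coding potential scores for the unannotated transcripts, and these were used only to describe the table. Class codes were read in their usual gffcompare sense: intronic (2323), intergenic (1282), new isoform sharing a splice junction with an annotated gene (847), exon overlap (255) and antisense (239). Of the new isoforms, 443 carried the name of a protein-coding gene. Messenger RNAs themselves are not among the transcripts of the table. In GENCODE release 29, 95.99% of the annotated transcripts were found by identifier, and 99.39% of these had the same length. The table has no positions, so coordinates below are those of GENCODE release 29 on GRCh38.

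Depth was worked out from the table. Coverage divided by FPKM was 1 constant per library, which equals its mapped gigabases. Coverage times length gave the bases on a transcript, and these were whole numbers within 0.01 for 86.4%, 86.95%, 87.14% and 86.35% of the single-exon unannotated transcripts in the control, 6, 12 and 24 h libraries. The most frequent base total below 1000 was 282 in each library, seen 14, 50, 18 and 16 times, and was taken as 1 read pair. On that reading the libraries held 35.2 M, 37.4 M, 27.8 M and 27.0 M mapped read pairs in the same order (M, mega). Read pairs of a gene are its bases divided by 282. Intervals at 95% for a ratio of read pairs are exact Clopper-Pearson intervals; they cover counting error only, because read pairs without molecular identifiers are not independent molecules and because no interval between cultures can be had from 1 library per group.

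With 1 library per group no test was run and no p-value is given. A fixed rule of size was used: a feature was past the rule when the log2 ratio of (FPKM + 1) to (control FPKM + 1) was at least 1 in size and the higher of both libraries had an FPKM of at least 1. On this scale the change of low features is understated. The features were transcripts, as in the table. Sums per gene were added after the data were examined, because isoforms of 1 locus often differed in opposite directions. They cover annotated transcripts and new isoforms of 7989 genes with at least 1 annotated transcript in the table; 106 genes with new isoforms alone were left out of the sums and of the lists, a choice also made after their values were seen. Clone names were completed with their version from GENCODE where the transcript identifier allowed it.

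Before the data were examined, the rule, the lists of genes and the rule for naming features were fixed. Named features are the 8 highest and the 8 lowest log2 ratios per time point among features past the rule with a gene name, the 5 higher and the 5 lower with the largest smallest change among those past the rule at all 3 times, and list members past the rule with further examples in order of mean FPKM. The same rule of 8 and 8 was applied to the sums per gene. A list needed 5 detected members, detected meaning an FPKM of at least 1 in any library. The median log2 ratio of a list was placed among 10000 random lists of the same size drawn from the same 10 bins of mean FPKM, as a description of these libraries. The lists were snoRNA host genes; hypoxia and HIF linked, p53 and DNA damage linked, estrogen receptor linked, MYC and proliferation linked, abundant nuclear, and stress response lncRNAs; microRNA host genes; fibroblast and leukocyte marker lncRNAs; and, in case messenger RNAs were present, glycolysis and HIF target, cholesterol synthesis, proton sensing, ATF4 and unfolded protein response, cell cycle and estrogen receptor target mRNAs. Transcripts linked to X inactivation and to the Y chromosome were counted and are not named, except FTX and JPX, which were on a list.

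The rule was tested on simulated data with Poisson read pairs for all 19870 transcripts, of which 200 were changed 4-fold in each comparison. The changed ones were drawn from transcripts clearly above the minimum FPKM of the rule, so recovery of the higher ones was nearly set in advance. At 6, 12 and 24 h the rule recovered 100.0% of the transcripts made higher at each time and 84.0%, 86.0% and 87.0% of those made lower, with 4, 0 and 6 unchanged transcripts past it. In 100 simulated sets of unchanged libraries at the real depths, a mean of 1.83, 4.16 and 4.35 transcripts passed the rule. These counts are what read sampling alone gives. The simulation left out the assignment of reads to isoforms, reads shared between copies of a gene and duplicate read pairs, so it does not measure technical noise as a whole.

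Alternatives fixed in advance were a pseudocount of 0.1, no filter on low values, a mean FPKM of at least 1 over the 4 libraries, rescaling by the median ratio of each library to the geometric mean of the 4 (6180 transcripts above 0 in all 4), rescaling to the same total, and a 4-fold threshold. The rescaling to the same total used the mean total of the 4 libraries, so that the pseudocount and the filter kept their meaning. Added after the data were examined were sums per gene and per locus, annotated transcripts alone, a scaling on the median of multi-exon annotated transcripts, genes with new isoforms alone, and leaving out the 6 h library. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.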

Results

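Long non-coding RNA was profiled in MCF7, an estrogen receptor-positive breast cancer cell line, to see how its levels differ after culture in acidic medium of pH 6.6. There were 4 libraries: 1 control (number 4 in the sample titles) and 1 each after 6 h (number 4), 12 h (number 5) and 24 h (number 2). No group had a replicate, so no spread between cultures, no test and no p-value could be had, and every difference below is one between single libraries. The labels give no time and no pH for the control, so time in culture and acid medium cannot be told apart. The depth implied by the table was 35.2 M read pairs in the control and 37.4 M, 27.8 M and 27.0 M at 6, 12 and 24 h. The 19870 transcripts of the table held 2.82%, 1.96%, 2.74% and 3.94% of the sequenced bases in that order. Of these transcripts, 5277 reached an FPKM of at least 1 in any library (563 annotated and 4714 unannotated), and 10017 were listed at 0 in all 4. Levels are given as FPKM, log2 ratios are of FPKM plus 1 against the control, and ratios of read pairs carry an exact Clopper-Pearson 95% interval that covers counting error only.

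The classes of transcript differed at 6 h. The 1302 intronic transcripts, unannotated RNA within introns of other genes, had a median log2 ratio of -0.56 at 6 h, 0.08 at 12 h and 0.26 at 24 h. Among multi-exon annotated lncRNAs (210 transcripts) the medians were -0.07, 0.05 and 0.02. Intergenic transcripts (666) stood at -0.37, 0.02 and -0.01, and antisense transcripts (158) at -0.50, 0.03 and 0.17. The number of intronic transcripts with an FPKM of at least 1 was 1351 in the control, 473 at 6 h, 1599 at 12 h and 1779 at 24 h. Rescaling each library by its median ratio to the geometric mean of all 4 moved the median log2 ratio by 0.47 at 6 h, by -0.06 at 12 h and by -0.14 at 24 h. This rescaling puts the median near 0 by construction (0.04 at 6 h), and intronic transcripts were the largest class. After that rescaling the 6, 12 and 24 h medians were -0.17, 0.01 and 0.09 for intronic and 0.53, -0.02 and -0.13 for multi-exon annotated transcripts. The sign for the spliced lncRNAs thus turned with the scaling at each time. Intronic transcripts stayed below the spliced lncRNAs at 6 h and above them at 24 h, an order that 1 factor per library can hardly change. Intergenic transcripts then stood at 0.12, -0.05 and -0.14, with the 6 and 12 h signs turned, and antisense transcripts at -0.07, -0.02 and 0.02, with the 12 h sign turned. Rescaling to the same total, or on multi-exon annotated transcripts, moved the median log2 ratio at 6 h by 0.05 only. The same-total factor leans on few abundant transcripts. At 6 h, 1 antisense transcript listed under NEMF held 3744 of the summed FPKM of 17231.8. In the control FP236383.3 held 3858 of 18387.4.

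**Figure D1:**
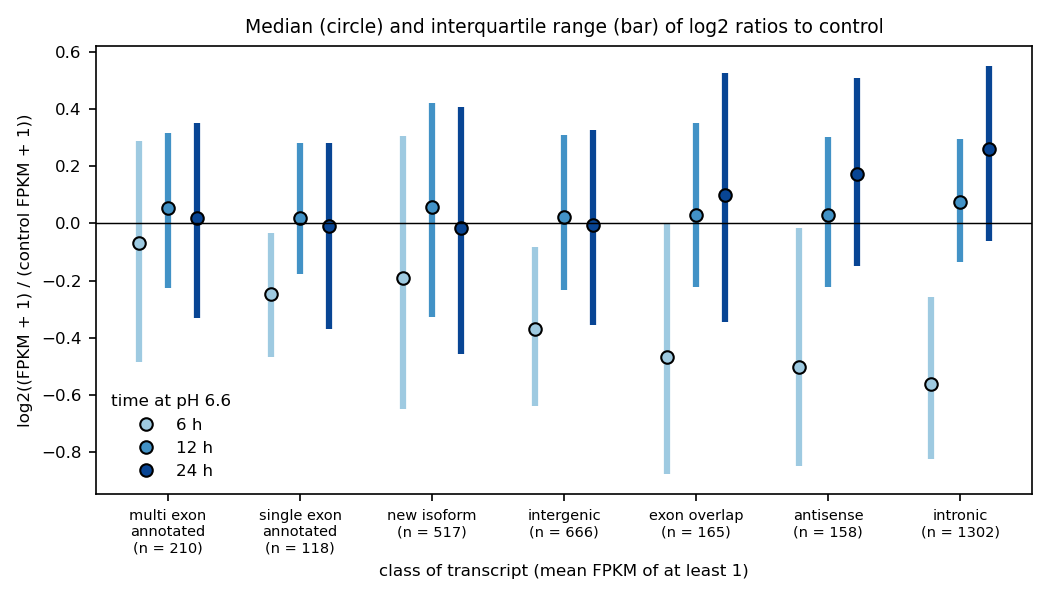
Median log2 ratio to the control (points) and range between the quartiles (bars) for each class of transcript at 6, 12 and 24 h, with FPKM as deposited and 1 library per time. The intronic median was -0.56 at 6 h and 0.26 at 24 h, and that of multi-exon annotated lncRNAs was -0.07 and 0.02; after rescaling by median ratios the latter were 0.53 and -0.13.

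After 6 h, 16 of the 17 named genes past the size rule were lower with FPKM as deposited. SNHG29, a snoRNA host gene, had an FPKM of 71.3 in the control and 32.0 at 6 h, a read pair ratio of 0.448 (0.418 to 0.479). MIR4435-2HG, a microRNA host gene, had 24.3 and 10.3 (ratio 0.550, 0.474 to 0.637). Its FPKM ratio was 0.422, so its read pairs fell less than its FPKM. FTX, a lncRNA of the X inactivation center, had 9.11 and 4.03 (0.468, 0.413 to 0.530), and LINC-PINT, a p53-induced lncRNA, had 2.76 and 0.861 (0.320, 0.232 to 0.436). MIR200CHG, which hosts microRNAs that maintain epithelial identity, had 36 read pairs in the control and was listed at 0 at 6 h, where the ratio was at most 0.102, yet it had 31 read pairs at 12 h and 20 at 24 h. These 5 genes lie at 2:111036776-111523376 (MIR4435-2HG), X:73946555-74293574 (FTX), 7:130876809-130913310 (LINC-PINT) and 12:6963246-6964447 (MIR200CHG) on GRCh38, and SNHG29 has no entry under that name in the annotation used.

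Summed per gene, 17 of 385 genes were past the size rule as lower and 1 as higher at 6 h. The gene that was higher, AL590705.3, rested on 1 read pair in the control and 23 at 6 h (ratio 21.7, 3.52 to 893). The other lower genes of the ranking were AC073046.1 (7.97 to 0.770), AC004233.3 (6.21 to 1.55), LINC01006 (8.79 to 2.61), AC138393.3 (2.67 to 0.460), AL391244.3 (4.38 to 1.25), AL132989 (4.60 to 1.39) and LINC02542, which had 39 read pairs in the control and 0 at every later time. The direction depended on the scaling: after rescaling by median ratios 40 genes were higher and 4 lower, among the latter AC073046.1, MIR200CHG and LINC02542, while SNHG29 (-0.26), MIR4435-2HG (-0.34), FTX (-0.25), LINC-PINT (-0.51) and LINC01006 (-0.74) kept their sign and no longer passed the rule. The 40 then included the snoRNA hosts GAS5 (1.27), SNHG16 (1.45), SNHG5 (1.20), SNHG1 (1.12) and SNHG8 (1.03) and the abundant cytoplasmic lncRNA NORAD (1.02), which were chosen for mention after their values were seen. Of the 17 named genes past the rule as deposited, 15 stayed past it with the same total and 15 with multi-exon scaling.

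Among single transcripts at 6 h, the ranks by log2 ratio held unannotated transcripts of several kinds. An unannotated antisense transcript listed under NEMF, whose locus is shared with AL627171, a gene that contains a copy of the signal recognition particle RNA gene, had an FPKM of 0.014 in the control and 3744 at 6 h, whereas another antisense transcript of that locus had 343 and 0.087. Of 2 new isoforms of PKIB, an inhibitor of protein kinase A, one had 0.067 and 39.0 and the other had 42.6 and 0.062. Other transcripts of the highest ranks lay at FP236383 (0.261 to 72.2), in UBC (0 to 31.3), at AL353759 (0.050 to 30.4), in RBX1 (0.650 to 32.0), at AP000924 (0 to 16.5) and at AC090950 (0 to 15.9). Those of the lowest ranks lay at RF00100 (93.5 to 0), MIR3648-1 (116 to 0.274), HIST1H2BK (79.0 to 0), FP236383 (69.3 to 0.119), FP671120 (61.5 to 0) and, antisense, at SCD, the gene of stearoyl-CoA desaturase (50.6 to 0.0037). HIST1H2BK, SCD, AL353759 and AP000924 had a locus sum equal to the transcript itself. Locus sums leave out messenger RNAs, so reads moved to or from the messenger RNA of a coding gene cannot be seen. Of the 37 transcripts named by rank over all times, 18 carry the name of a coding gene. FP236383, FP671120 and MIR3648-1 lie in the ribosomal RNA gene repeats of chromosome 21, whose copies share reads.

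By the size rule, 701 of 3568 eligible transcripts differed at 6 h, 171 higher and 530 lower (20 and 28 of them annotated), against a mean of 1.83 in simulated unchanged libraries. This split turned to 479 higher and 214 lower after rescaling by median ratios. It did not turn with the same total (188 higher and 472 lower) or the scaling on multi-exon annotated transcripts (192 and 480).

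After 12 h, MAPKAPK5-AS1, which overlaps the start of the kinase gene MAPKAPK5, had an FPKM of 13.3 against 1.59 in the control (read pair ratio 6.08, 4.77 to 7.84), and HIF1A-AS2, antisense to the gene of the hypoxia-inducible factor HIF1A, had 1.40 against 0.130 (10.8, 7.82 to 15.3). LINC01719 had 5.80 against 1.54 (3.99, 3.19 to 5.02). H19, an imprinted growth-linked lncRNA, was lower at 12 h alone, with 1.94 against 10.8 in the control (0.180, 0.148 to 0.218), 10.5 at 6 h and 10.4 at 24 h. LINC01006 had 2.05 against 8.79 (0.201, 0.157 to 0.254). The protocols do not say whether the libraries keep the strand, so reads of MAPKAPK5-AS1 and HIF1A-AS2 cannot be separated from those of their sense partners. These genes lie at 12:111839764-111842902 (MAPKAPK5-AS1), 14:61715558-61751097 (HIF1A-AS2), 1:146052566-146061948 (LINC01719), 11:1995176-2001470 (H19) and 7:156472196-156640654 (LINC01006).

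Summed per gene, 11 of 449 genes were higher and 10 lower at 12 h. The other higher genes of the ranking were AC092368.3 (1.72 to 5.49), DUXAP8 (3.24 to 8.93), RAB30-AS1 (3.02 to 7.90), AC092910.3 (0.900 to 3.21), AL359258.1 (0 to 1.30) and LINC01087, which had 0 read pairs in the control and 168 at 12 h. For DUXAP8 the read pair ratio was 1.79 (1.585 to 2.015), below its FPKM ratio of 2.76. The other lower genes included AC073046.1 (7.97 to 0.477), AL391244.3 (4.38 to 0.272), Z93241.1 (7.22 to 1.5), AL162595 (1.8 to 0), LINC02542 and FP236383.3, which lies in the ribosomal RNA repeats and had 3858 in the control and 694.0 at 12 h. After rescaling by median ratios 8 genes were higher and 10 lower, 18 of the 21 stayed past the rule, and HIF1A-AS2 did not (log2 ratio 0.96).

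Among single transcripts at 12 h, the highest ranks included 2 at FP236383 (0.261 to 488 and 0 to 39.8), 1 at FP671120 (0 to 117) and new isoforms of UBE2K (0.031 to 28.3), ISCA1 (0.001 to 20.4), SMIM14 (0 to 15.0), ATG12, an autophagy gene (0.196 to 17.9), and HMGN4, a nucleosome-binding protein gene (0.993 to 30.2). The locus sum of SMIM14 was 26.3 in the control and 25.1 at 12 h. The lowest ranks lay at RF00100 (93.5 and 27.1 to 0), HIST1H2BK (79.0 to 0), FP236383 (69.3 to 0.0020), SCD (50.6 to 0), AC090950 (32.6 to 0), AC011603 (24.0 to 0) and FAM102B (64.1 to 0.067). By the size rule, 561 of 4396 eligible transcripts differed, 321 higher and 240 lower (25 and 24 annotated), against a simulated mean of 4.16. After rescaling by median ratios 227 were higher and 230 lower. The same total gave 351 higher and 229 lower, and the scaling on multi-exon annotated transcripts 280 and 251.

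After 24 h, 2 of 5 detected members of the abundant nuclear list and 2 of 12 microRNA hosts were past the size rule as higher. That nuclear list also holds NORAD, named above as cytoplasmic. MALAT1, a nuclear speckle lncRNA, had an FPKM of 801.2 against 296.0 in the control (read pair ratio 2.76, 2.74 to 2.79), and NEAT1, the scaffold of paraspeckles, had 6.25 against 1.85 (3.70, 3.46 to 3.96). HIF1A-AS2 had 2.77 against 0.130 (14.7, 10.7 to 20.7). MIR34AHG, the host of a p53-induced microRNA, had 4.68 against 1.44 (3.22, 2.75 to 3.79), and MIR29B2CHG, also a microRNA host, had 2.12 against 0.532 (3.93, 3.42 to 4.54). The library at 24 h also held more intronic RNA; the intronic median was 0.26. These genes lie at 11:65497688-65506516 (MALAT1), 11:65422774-65445540 (NEAT1), 1:9148011-9198906 (MIR34AHG) and 1:207801518-207879096 (MIR29B2CHG).

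**Figure D2:**
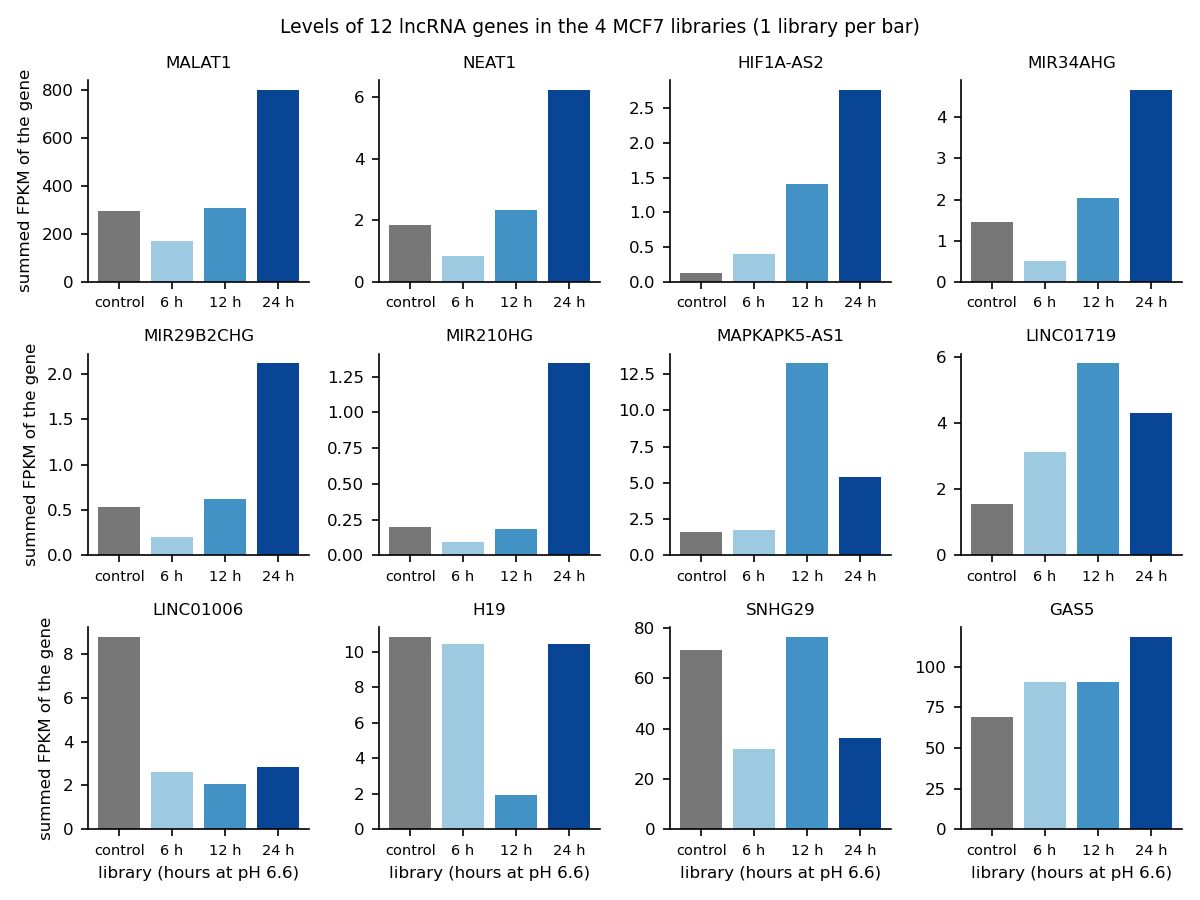
FPKM of 12 named lncRNA genes (bars, summed over transcripts, linear axis from 0) in the control and at 6, 12 and 24 h in pH 6.6 medium, 1 library each. HIF1A-AS2 stood at 0.130, 0.393, 1.40 and 2.77, MALAT1 at 296.0, 168.5, 308.2 and 801.2, and H19 at 10.8, 10.5, 1.94 and 10.4; the lower 6 h value of MALAT1 turned to a log2 ratio of 0.079 after rescaling by median ratios.

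Summed per gene, 20 of 473 genes were higher and 7 lower at 24 h. The other higher genes of the ranking were AL117329 (2.15 in the control, read pair ratio 5.17), AC092368.3 (1.72 to 6.93), AC015813.1 (0.264 to 2.65), MAPKAPK5-AS1 (1.59 to 5.43) and C5orf56 (0.459 to 2.63). The lower genes were AP002360.1 (3.73 to 0.129), AL133215.2 (1.94 to 0.125), CU633967.1 (1.63 to 0.025), LINC01006 (8.79 to 2.87), LINC02542, LINC01963 (9.24 to 3.5) and TRAM2-AS1 (2.91 to 0.837). After rescaling by median ratios the split turned to 12 higher and 16 lower. Of the 27 genes 19 stayed past the rule, among them MALAT1 (1.19), NEAT1 (1.11) and HIF1A-AS2 (1.47), whereas MIR34AHG (0.98) and MIR29B2CHG (0.82) did not.

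Among single transcripts at 24 h, the highest ranks included 3 at FP236383 (0 to 1027, 0.261 to 167 and 0 to 99.2), 1 at AL627171 (0 to 174), new isoforms of H2AFZ, a histone variant gene (0 to 55.3), SMIM14 (0 to 23.8) and HMGN4 (0.993 to 39.3), and the annotated GAS5 transcript ENST00000448718 (0.196 to 19.7). The locus sum of SMIM14 moved little, from 26.3 in the control to 28.7 at 24 h. The lowest ranks lay at AL627171 (343 to 0.360), RF00100 (93.5 and 27.1 to 0), HIST1H2BK (79.0 to 0.876), FAM102B (64.1 to 1.46), SCD (50.6 to 0.0010), PKIB (42.6 to 0.012) and in SHCBP1L (23.9 to 0.397). By the size rule, 647 of 4527 eligible transcripts differed, 398 higher and 249 lower (36 and 24 annotated), against a simulated mean of 4.35. This split turned to 234 higher and 268 lower after rescaling by median ratios. It did not turn with the same total (318 higher and 272 lower) or the scaling on multi-exon annotated transcripts (375 and 257).

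At all 3 times, LINC01006 and LINC02542 were the genes past the size rule as deposited, both lower, and no gene was higher throughout; after rescaling by median ratios LINC01006 no longer passed at 6 h (-0.74) and LINC02542 did at each time. At 12 and 24 h together 5 genes were higher (HIF1A-AS2, MAPKAPK5-AS1, LINC01719, AC092368.3 and AL031281.3) and 3 lower (LINC01006, LINC02542 and AL133215.2). After rescaling by median ratios, MAPKAPK5-AS1, AC092368.3 and the 3 lower genes stayed past the rule at both times; HIF1A-AS2 (0.96 at 12 h), LINC01719 (0.83 at 24 h) and AL031281.3 (0.95 and 0.98) did not. Among single transcripts the higher ones with the largest smallest change were at FP236383 (0.261 in the control, then 72.2, 488 and 167), new isoforms of HMGN4 (0.993, 26.8, 30.2 and 39.3) and of RPS14, a ribosomal protein gene (0.955, 13.4, 21.6 and 19.5), and annotated transcripts of GAS5 (ENST00000432536, 0.188, 5.59, 8.09 and 7.43) and HEIH (ENST00000623091, 0.448, 7.51, 7.07 and 4.76). The sum over HEIH moved less, with 5.51 in the control and 7.57, 7.28 and 5.33 later. The lower ones were at RF00100, SCD, HIST1H2BK and MSRB2 (14.9 in the control, then 0, 0.046 and 0.011).

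In total 105 transcripts were past the rule in 1 direction at all 3 times, 24 higher and 81 lower. The product of the single shares gave 0.785 and 1.14, and simulated unchanged libraries against a shared control gave means of 0.02 and 0. The 3 comparisons share 1 control library, and taking 6, 12 or 24 h as the shared library in its place gave 235, 150 and 195 such transcripts; without the 6 h library 198 transcripts were past the rule at 12 and 24 h.

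Of the gene lists, the hypoxia and HIF linked lncRNAs stood highest at 24 h, with a median log2 ratio of 0.68 over 8 detected members, at percentile 99.49 of random lists matched on level. Its members HIF1A-AS2, MALAT1 and NEAT1 were past the rule as higher, and none passed it as lower; 6 of the 8 stood above the control, and FTX (7.14 against 9.11) and H19 (10.4 against 10.8) stood below it. MIR210HG, the host of a hypoxia-induced microRNA, chosen for mention after its values were seen, had an FPKM of 1.34 against 0.195 (read pair ratio 6.61, 3.69 to 12.7) and a log2 ratio of 0.97, while CYTOR had 16.0 against 11.9. Matched lists of intronic transcripts had a median of 0.29 at 24 h, and among these the list stood at percentile 96.17. At 6 and 12 h its medians were -0.14 (percentile 60.08, FTX past the rule as lower) and 0.06 (percentile 53.99, HIF1A-AS2 higher and H19 lower), and after rescaling by median ratios both signs turned, to 0.32 and -0.03. With members that were not detected included, the 24 h median was 0.14.

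The 12 detected microRNA host genes had a median of -0.50 at 6 h (percentile 2.34), where 0 of 12 were above the control and MIR4435-2HG was past the rule. At 12 h the median was -0.03 (percentile 23.08), and at 24 h it was 0.28 (percentile 97.65), with MIR34AHG and MIR29B2CHG past the rule as higher. None of these 3 genes passed the rule after rescaling by median ratios (-0.34, 0.98 and 0.82). MIR503HG had 1.92 in the control and 0.924, 3.05 and 2.97 later, and MIR181A1HG had 2.97, 1.72, 2.5 and 2.28. The 6 h median was -0.062 after rescaling by median ratios, at percentile 0.35, so its low standing among matched lists remained. Intronic transcripts, with medians of -0.56 and 0.26 at 6 and 24 h, moved the same way as this list.

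The 6 detected p53 and DNA damage linked lncRNAs had medians of -0.46, 0.10 and 0.38 at 6, 12 and 24 h (percentiles 10.97, 53.91 and 96.27). The 6 h sign turned to 0.19 after rescaling by median ratios. As deposited, LINC-PINT was past the rule as lower at 6 h, where it was -0.51 and not past the rule after the rescaling, and MIR34AHG (0.98 after it) and NEAT1 were past it as higher at 24 h. PVT1, next to MYC, had 13.4 in the control and 10.8, 11.6 and 23.3 later, and NORAD had 65.0, 71.7, 63.9 and 58.2. Including undetected members moved the 24 h median to 0.012, at percentile 57.91.

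The 18 detected snoRNA host genes, which are spliced and tied to growth and translation, had medians of 0.05, 0.13 and 0.09 (percentiles 93.49, 75.21 and 68.63), and the 24 h sign turned to -0.13 after rescaling by median ratios. The 6 h median was then 0.65, at percentile 51.78, so the standing at 6 h depended on the scaling. As deposited, SNHG29 at 6 h was the only member past the rule. GAS5, a growth arrest linked host, had 69.3 in the control and 90.8, 90.4 and 118.3 later, and SNHG8 had 57.1, 63.4, 49.7 and 52.0. The 6 estrogen receptor linked lncRNAs had medians of 0.02, 0.20 and -0.04 (percentiles 90.56, 82.68 and 37.98), with H19 at 12 h past the rule as lower and GATA3-AS1 at 1.91 in the control and 2.62, 2.74 and 2.41 later. DSCAM-AS1, left out because it had new isoforms alone, was past the rule as lower at 6 h (-1.08), though not after rescaling by median ratios (-0.21); with it the 6 h median was -0.0009. The 5 MYC and proliferation linked lncRNAs had medians of -0.42, -0.20 and 0.11 (percentiles 9.20, 15.35 and 72.97), none past the rule, and after rescaling by median ratios the 6 and 24 h signs turned, to 0.41 and -0.09. The 5 abundant nuclear lncRNAs had -0.63, 0.06 and -0.16 (percentiles 3.68, 50.49 and 26.52), with FTX lower at 6 h and MALAT1 and NEAT1 higher at 24 h, where JPX stood at 3.33 against 6.85 in the control. Rescaling by median ratios turned the 6 h median to 0.079 and the 12 h median to -0.053. The list also held NORAD, named above as cytoplasmic, whose 24 h value of -0.40 after that rescaling was the list median. The 6 stress response lncRNAs had -0.17, 0.29 and 0.18 (percentiles 55.43, 88.44 and 84.97), with NEAT1 higher at 24 h, and the 6 h sign turned to 0.50. NEAT1 is on 4 of these lists and MALAT1, FTX, H19, PVT1, NORAD and MIR34AHG are each on more than 1, so the lists are not independent.

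**Figure D3:**
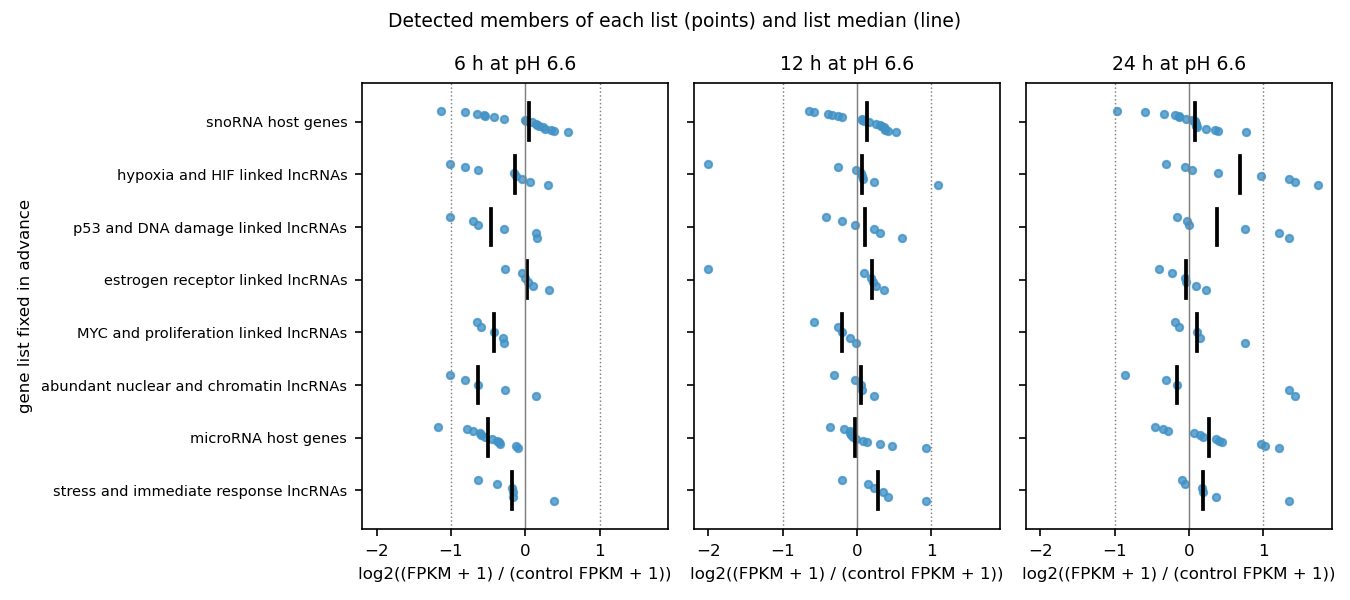
Log2 ratio to the control of each detected member (points) and the median (lines) for 8 gene lists at 6, 12 and 24 h, FPKM as deposited, 1 library per time. The hypoxia linked list had medians of -0.14, 0.06 and 0.68, the first and second of which turned to 0.32 and -0.03 after rescaling by median ratios, and the microRNA hosts had -0.50, -0.03 and 0.28.

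Markers of other cell types were scarce. Of 14 fibroblast marker lncRNAs 1 was detected, MIR503HG, which is also a microRNA host gene and is not restricted to fibroblasts, and of 13 leukocyte marker lncRNAs 0 were detected. The lists of messenger RNAs had 0 members with an annotated transcript, since the table holds non-coding transcripts.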

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

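All tests of explanations in this part were chosen after the results were seen. None of the differences between times below was tested, since each time has 1 library.

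Transcripts that stood past the size rule in opposite directions at different times numbered 19 for lower at 6 h and higher at 24 h and 8 for higher at 6 h and lower at 24 h. There were 5 lower at 6 h and higher at 12 h, 4 higher at 6 h and lower at 12 h, 3 lower at 12 h and higher at 24 h, and 4 higher at 12 h and lower at 24 h. Summed per gene, 0 genes did so with FPKM as deposited, whereas after rescaling by median ratios Z93241.1 was past the rule as higher at 6 h (1.17) and as lower at 12 h (-1.74) and 24 h (-1.01). The median log2 ratio of the microRNA host genes was -0.50 at 6 h and 0.28 at 24 h.

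The median log2 ratio of intronic transcripts was -0.56 at 6 h and 0.26 at 24 h. The values argue against both lower depth and a single scale factor at 6 h. That library held 37.36 M implied read pairs against 35.22 M in the control. A single factor would move intronic and level-matched multi-exon annotated transcripts alike, yet their gap was -0.45 (95% bootstrap interval -0.50 to -0.41). The interval is too narrow, because the 210 multi-exon transcripts were redrawn as often as the more numerous intronic ones. Several transcripts of 1 gene were also taken as independent. An even cover of genomic DNA in the control, high enough for the median intronic fall of 0.77, would reach every locus. Yet 86.29% of 1349 single-exon annotated transcripts had a control FPKM below that fall, and 41.36% were at 0. The fall came from intronic transcripts with a mean FPKM of at least 1, and the single-exon ones had no such filter. Less or uneven DNA was therefore not tested. A smaller share of nuclear and unspliced RNA in the 6 h library may account for the pattern. MALAT1, which is retained in the nucleus, had a log2 ratio of -0.81, beside a median of -0.07 for multi-exon annotated transcripts. Its sign rests on the scaling, because after rescaling by median ratios the values were 0.079 and 0.53. MALAT1 stood below that median either way, but it is 1 gene. The rescaling is no second check of this order, because 1 factor moves the whole library. The explanation stays open, and whether such a share would come from the cells in acid medium or from handling cannot be told apart with 1 library.

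Of the calls of single transcripts, 208, 199 and 224 at 6, 12 and 24 h lay at loci with several transcripts that reached an FPKM of 1 in some library, such as PKIB, FP236383 and AL627171, and 493, 362 and 423 at loci with 1. Of the 631 calls at loci with several over the 3 times, 33.44% (Clopper-Pearson 95% interval 29.76 to 37.27) had a locus total past the rule in the same direction. The interval takes the calls as independent and is too narrow, because the times share 1 control library and the same loci recur. Reads of a locus assigned to another of its isoforms are a candidate explanation for the rest of these 631, and no biological change of splicing was tested against it. The test says nothing about calls at loci with 1 such transcript, such as HIST1H2BK, SCD and H2AFZ. It also leaves out messenger RNAs, so reads moved to or from those of coding genes were not tested.

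The hypoxia linked lncRNAs had a median log2 ratio of 0.68 over 8 members at 24 h. Set against level-matched lists of intronic transcripts, whose median was 0.29, the list stood at percentile 96.17, so a general shift of intronic RNA in that library cannot be told apart from a change of the list with 8 members. More transcription of HIF target genes stays open: the 4 intronic transcripts in PDK1, PFKFB4, PFKFB3 and PKM, enzymes of glucose metabolism, had a median of 1.24, at percentile 99.94 of matched intronic transcripts with a median of 0.32, but they are fewer than the 5 members a list needed. PDK1, PFKFB4 and PFKFB3 reached an FPKM of 1 at 24 h alone, and the 4 values were seen before the test was chosen, so it decides nothing. Acid medium, cell density and oxygen use over 24 h stay open because the labels name no control matched in time.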

How the results depend on the processing

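The settings chosen after the data were examined are the sums per gene and per locus, annotated transcripts alone, genes with new isoforms alone, the scaling on multi-exon annotated transcripts and the count without the 6 h library. No paired analysis was possible because the control and 6 h libraries alone share a number and each group has 1 library. The cause of the differences was not tested except where the setting itself reduces or adds features.

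The counts past the size rule were 701, 561 and 647 at 6, 12 and 24 h and 105 at all 3 times. In the same order they were 1859, 1232, 1623 and 228 with a pseudocount of 0.1, and 106, 121, 116 and 35 with a 4-fold threshold. Sums per gene, which have fewer features, gave 18, 21, 27 and 2, and with genes of new isoforms alone 29, 33, 40 and 3. Annotated transcripts alone gave 48, 49, 60 and 9. A mean FPKM of at least 1 gave 270 at 12 h, 356 at 24 h and 65 at all 3 times. Sums per locus gave 60 at all 3 times, and 198 transcripts were past the rule at both 12 and 24 h. No filter on low values changed no count, because the rule itself needs an FPKM of 1. The other settings stayed within 1.5 times of the count. Rescaling by median ratios turned the split at 6 h from 24.39% to 69.12% higher, at 12 h from 57.22% to 49.67% and at 24 h from 61.51% to 46.61%. The same total gave 28.48%, 60.52% and 53.9%, and the scaling on multi-exon annotated transcripts 28.57%, 52.73% and 59.34%, so neither turned a split. The 12 h split also turned with the 4-fold threshold (46.28%) and the mean filter (49.26%).

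Rescaling by median ratios moved 11 of 24 medians: at 6 h to 0.65 for snoRNA hosts, 0.32 for hypoxia, 0.19 for p53, 0.60 for estrogen receptor, 0.41 for MYC, 0.079 for nuclear, -0.062 for microRNA host and 0.50 for stress lists, at 12 h to -0.053 for nuclear, and at 24 h to -0.13 for snoRNA hosts and -0.20 for estrogen receptor. The same total gave snoRNA hosts 0.31 at 12 h and -0.047 at 24 h. A pseudocount of 0.1 gave -0.38 for hypoxia and -0.88 for microRNA hosts at 6 h, and a mean FPKM of at least 1 gave hypoxia -0.39 at 6 h. With no filter, hypoxia was 0.14 at 24 h, p53 was 0 at 6 h and 0.012 at 24 h, MYC was -0.25 at 6 h and -0.057 at 12 h, nuclear was -0.19 and microRNA hosts -0.38 at 6 h. Scaling on multi-exon transcripts gave MYC -0.32 at 6 h. The estrogen receptor list had under 5 members, and so no value, with the mean filter and the multi-exon scaling. Over the alternatives that gave a value, the lowest and highest percentiles at 6, 12 and 24 h were, for snoRNA hosts, 51.78 to 97.72, 73.05 to 86.27 and 54.47 to 76.9, for hypoxia, 10.69 to 70.76, 49.53 to 66.28 and 93.81 to 99.94, for p53, 5.94 to 80.83, 37.73 to 58.95 and 57.91 to 97.82, for estrogen receptor, 88.14 to 96.66, 77.97 to 88.47 and 32.05 to 43.53. They were, for MYC, 9.84 to 32.69, 12.16 to 20.16 and 63.9 to 79.99, for nuclear, 1.29 to 17.28, 37.6 to 59.56 and 20.12 to 54.12, for microRNA hosts, 0.24 to 2.15, 14.22 to 31.45 and 90.3 to 97.81 and, for stress, 52.36 to 63.41, 87.61 to 94.06 and 77.25 to 87.57.

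Of the named genes, 4 of 17 at 6 h, 18 of 21 at 12 h and 19 of 27 at 24 h stayed past the rule after rescaling by median ratios, and 0 turned direction. With a pseudocount of 0.1 all stayed; with the same total 15, 20 and 23 did, and with multi-exon scaling 15, 20 and 27. In simulated data a 4-fold lower level was recovered in 84.0% to 87.0% of cases and a 4-fold higher level in all. The changed transcripts were drawn from those clearly above the minimum FPKM of the rule, and depth was not varied. Read sampling alone put a mean of 1.83, 4.16 and 4.35 simulated transcripts past the rule. Isoform assignment, shared reads and duplicates were not simulated, and single libraries leave the spread between cultures unknown.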

Other observations

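The tests of explanations were chosen after the results were seen, and the values below have no test, with 1 library per time and FPKM as deposited. Of genes with intronic transcripts, 10 had at least 3 past the rule as lower at 6 h, and their sums at 24 h went both ways. They were chosen for mention after their values were seen. A gene with more intronic transcripts had more chances to reach 3, and intronic transcripts as a class had a 6 h median of -0.56. BCAS3, USP32 and TRIM37 lie close together on chromosome 17, and NCOA3 and SULF2 on chromosome 20. Their copy number was not examined. Summed over 8 intronic transcripts of NCOA3, a coactivator of nuclear receptors, the FPKM was 24.4 in the control and 6.78, 30.2 and 70.6 at 6, 12 and 24 h, with 5 of them past the rule as lower at 6 h and 6 as higher at 24 h. The 13 intronic transcripts of BCAS3 gave 32.4, 8.65, 27.2 and 54.6, the 6 of TRIM37, a ubiquitin ligase, 27.2, 8.60, 24.8 and 40.7, and the 6 of USP32, a deubiquitinase, 16.3, 4.53, 16.5 and 31.6. At 24 h the sums of SULF2 (16.0 in the control and 20.7), CCDC200 (25.7 and 26.0), ATF7IP2 (6.93 and 9.60) and ELF1 (7.98 and 10.1) were above the control by less, and those of LRP1B (9.93 and 6.30) and PLCB1 (7.44 and 5.97) were below it. In AHNAK, a large scaffold protein gene, the 14 intronic transcripts gave 18.6, 16.8, 20.5 and 44.8, with 4 past the rule as higher at 6 h and 7 at 24 h. After rescaling by median ratios CCDC200 fell below the control at 24 h (23.0 and 19.7), ELF1 had 7.16 and 7.68, SULF2 14.4 and 15.7, and AHNAK rose at 6 h (16.7 and 27.9); NCOA3, BCAS3, TRIM37 and USP32 stayed lower at 6 h and higher at 24 h. As deposited, the introns of MIR34AHG, the host of a p53-induced microRNA, gave 3.87, 1.72, 6.69 and 18.3, following the spliced gene.

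Intronic transcripts within genes of the messenger RNA lists were few. Those of the glycolysis and HIF target genes were PDK1 (0.0746 in the control and 2.22 at 24 h), PFKFB4 (0.153 and 2.76), PFKFB3 (0.757 and 2.09) and PKM (1.02 and 2.76), with medians of -0.41 at 6 h, -0.01 at 12 h and 1.24 at 24 h. The 4 in cell cycle genes (TOP2A, TYMS, RRM2 and AURKA) had medians of -0.74, 0.52 and -0.07, and the 3 in the estrogen receptor targets GREB1 and ESR1 had -0.64, 0.16 and 0.46. The cholesterol synthesis, proton sensing and unfolded protein response lists had 0 intronic transcripts. Among genes with new isoforms alone, DSCAM-AS1, an estrogen receptor linked lncRNA, had 57.2 in the control and 26.6, 82.3 and 59.0 later, and GABPB1-AS1, a stress-linked lncRNA, was listed at 0 except for 1.46 at 12 h.

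The 6 h library stood further from both later libraries than these stood from each other. Against the control the counts at 6, 12 and 24 h were 701, 561 and 647 as deposited, and 693, 457 and 502 after rescaling by median ratios. By the size rule 1669 transcripts differed between 6 and 24 h, 1468 of them higher at 24 h, and 1061 differed between 6 and 12 h, against 627 between 12 and 24 h. The numbers after rescaling by median ratios were 1186, 860 and 472, and the direction turned: of the 1186, 396 were higher at 24 h and 790 lower. Rescaling to the same total kept the direction, with 1143 higher at 24 h and 241 lower. The 10 most abundant transcripts held 50.46% of the summed FPKM at 6 h and 38.1%, 29.09% and 34.43% in the control, 12 h and 24 h libraries.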
